A study of Mus musculus with 58 samples.

How the data were processed

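Left hemibrain RNA of male C57BL/6j mice was measured on 2-colour Agilent arrays against a common reference RNA pooled from 11 mouse cell lines. Per the labels, mice received from 3 weeks of age, for 24 weeks, a diet enriched in n-3 polyunsaturated fatty acids (ERD, n3:n6 of 7:1), a balanced diet (BLD, 1:1) or a standard laboratory diet (STD, 1:6). The titles divide each diet into set 1, with a control arm and an arm labelled 6 weeks, and set 2, with a control arm and an arm labelled 1 day. What the animals of those arms received is not given in the sources used here. Each sample carries its own animal number, which names the arrays below, so no samples were paired.

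Of 58 samples, 53 had a scanner file and entered every comparison. The other 5 had values in the series matrix alone and entered only the alternative that uses that matrix. The scanner files hold spot and local background intensity for both dyes, and the flags of Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 10.7 per the submitters' processing notes. The deposited series matrix holds log10 ratios of red (Cy5) over green (Cy3): its values lay within 0.005 of the scanner files' own log ratio, and its column medians ran from -0.0289 to 0. Its scale, centring and direction are therefore those of Feature Extraction. The dye labels of 37 samples read Cy3 for the reference and Cy5 for the hemibrain, and those of the other 21 count upward from sample to sample. Snap25, Mbp and Gfap, genes abundant in brain, were above the reference on all 53 arrays (Snap25 log2 ratio 2.08 to 5.43), so all arrays were read as hemibrain over reference. Dyes were not swapped, and a dye effect common to all arrays cancels in the differences between groups.

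Ratios were made with limma 3.58.1 in R 4.3.3. The plan fixed before the data were examined named mean signals, but the files give median signals, which were used with the median local background. Background was corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0. Spots marked as outliers were left out, and spots of one probe were averaged. Of 55681 probes, 27656 were named through their accession with the reference gene table, and 28025 kept the target name in the files. A probe was kept where the hemibrain channel was well above background on a share of at least 0.5 of the arrays of at least 1 group, which left 30275 probes. The brightest passing probe stood for its gene, giving 22977 genes or targets, of which 14756 carry a symbol. Where several probes of a gene passed, their disagreement is given beside the counts.

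The fit (lmFit and eBayes) had 1 mean for each of 12 groups of diet, set and arm. A diet contrast averages the 4 set-and-arm groups of a diet, and an arm contrast compares an arm with the control arm of its own set, within a diet or averaged over the 3 diets. Differences between diets in an arm effect were tested with the moderated F of limma. Values are log2 differences with the standard error (SE) of the fit, and group values are means ± SD. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05, and every gene-level adjusted p is from limma. Gene lists, 42 in number, for pathways, cell types and brain regions, were tested with camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the data. Their adjusted p-values are over the lists of a contrast.

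Genes named were chosen by a rule fixed before the data were examined: the 8 largest rises and falls past the threshold (3 within a diet), or the 3 smallest p-values on a side where fewer than 3 passed; up to 4 members of each list past the threshold; and sets of lipid genes and of activity and glucocorticoid genes given whatever their values. Some genes that the rule selects are not reported here. Also fixed then were the groups, contrasts, lists and most alternatives. The alternatives were other signals, normalizations, filters and probe rules, slide and scan day as blocks, array weights, the series matrix, only the groups of a contrast, control arms alone, and leaving out 1 array at a time. Chosen after seeing the data were scaling between arrays, hemibrain brightness as a covariate, a normexp offset of 20, leaving each set-and-arm group out of the diet contrasts, and matching groups within slides. The files placed the arrays on 8 slides and 2 scan days. Most slides held several groups, so results are given with slide as a block and within slides. Plain differences within slides mix diets, sets or arms, so those given compare, on 1 slide, diets within one set and arm or arms within one diet, averaged over such pairs of groups. Some rest on 1 array a side.

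The hemibrain channel was dim. Its median net signal per array ran from 3 to 21, with a median of 7, against 39.5 to 87 for the reference, and 15997 to 33607 probes per array were well above background. No probe was saturated in the hemibrain channel. The fit was tested on simulated data with the spread of the real arrays and 22977 genes. For ERD against STD it recovered 86.6% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1, with 18 false calls. For 6 weeks against control in ERD it recovered 44.8% and 88.1%, with 3 false calls. A shift of 0.1 added to the fatty acid oxidation list was recovered with an adjusted p of 1.2e-07 in camera, and 0 other lists were called. The simulated genes were drawn independently of each other. In the real data the estimated correlation was 0.02 for this list and 0.54 for ependymal genes, so the simulation does not show how often correlated lists are called falsely.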

Results

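The 53 arrays comprised 17 from ERD, 18 from BLD and 18 from STD hemibrains. In ERD there were 5 set 1 controls, 5 6 weeks arrays, 3 set 2 controls and 4 1 day arrays. In BLD there were 5, 5, 4 and 4, and in STD 4, 4, 5 and 5. Most arrays correlated closely, with a median r across genes of 0.967 for pairs of one group and 0.961 for pairs of different groups. The lowest mean r with the other arrays was 0.873 and 0.878, for BLD set 2 controls 457 and 458. Next came ERD set 1 control 413 at 0.882, which also had the fewest probes well above background (15997). It was followed by BLD set 1 control 425 (0.910), ERD set 1 controls 414 and 416 (0.9155 and 0.9162), BLD 6 weeks 432 (0.919) and BLD set 1 control 424 (0.924). The median for pairs on one slide was 0.969. The first principal component held 23.1% of the variance. Slide accounted for a share of 0.431 of it and diet for 0.0667, and its absolute r with the brightness of the hemibrain channel was 0.847. The median net hemibrain signal was 8.12 ± 4.41 in ERD, 9.06 ± 3.28 in BLD and 7.69 ± 3.90 in STD (mean ± SD over arrays). Of the 8 slides 6 lacked 1 of the diets, so the comparisons are also given with slide as a block. Scan day 2 comprised slide 7 (7 BLD, 0 ERD and 1 STD array) and slide 8 (3 BLD, 4 ERD and 1 STD array). Scan day was thus uneven between diets as well, above all between BLD and STD, and counts that moved with it as a block are given further below.

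The first comparison asked how the n-3 enriched diet differed from the standard diet. Angptl4, a secreted inhibitor of lipoprotein lipase and a target of PPAR transcription factors, was higher in ERD by 0.63 ± 0.09 (log2, SE; adjusted p = 0.000754). Its log2 ratio was -1.52 ± 0.36 in ERD (SD, n = 17) and -2.15 ± 0.21 in STD (n = 18), and 17 of 17 ERD arrays lay above the STD median. Creg2 was lower, with a log2 difference of -0.999 ± 0.155 (adjusted p = 0.000836; 16 of 17 arrays below the STD median). Tatdn2 (-0.50 ± 0.10) and Srp9, a subunit of the signal recognition particle (-0.38 ± 0.07), were lower too, both with an adjusted p of 0.0334. These 4 were the only genes of 22977 past the threshold, 1 higher and 3 lower, while 1616 had an unadjusted p below 0.05.

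**Figure D1:**
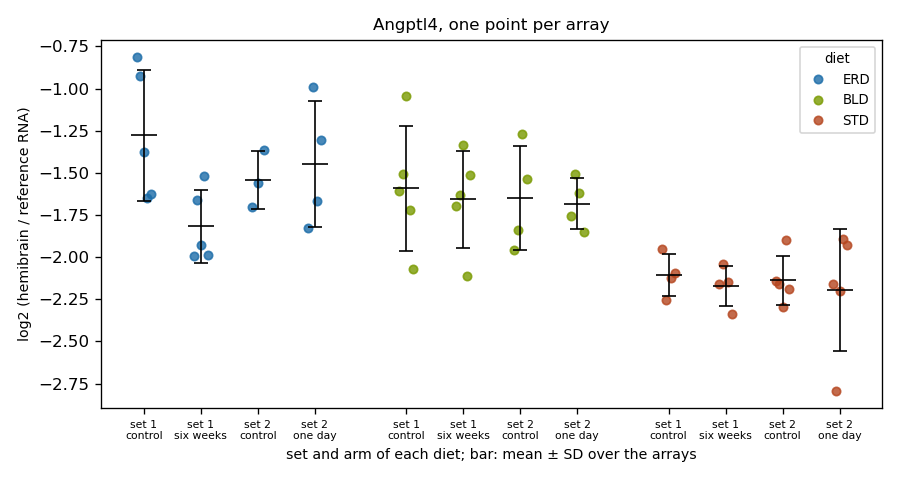
Angptl4 log2 ratio of hemibrain over reference RNA on each array (points), with the mean and SD (bars) of each diet, set and arm. Group means ran from -1.82 to -1.28 in ERD and from -1.68 to -1.59 in BLD, against -2.20 to -2.11 in STD.

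The list of fatty acid oxidation genes and PPAR targets was higher as a group in ERD than in STD. Of its 31 measured members, 24 lay above 0, with a median of 0.10 (adjusted p = 1.67e-06, and adjusted p = 0.000369 with an estimated correlation). Angptl4 was the 1 member that rose over all genes, and 3 rose when adjusted over the list alone. With slide as a block the list had an adjusted p of 0.000756, and its mean difference between diets of one set and arm lay above 0 on 4 of 4 slides (0.03 to 0.16). The endocannabinoid list (12 of 13 members below 0, median -0.11, adjusted p = 0.0298) and the GABA list (21 of 26 below 0, median -0.11, adjusted p = 0.019) were lower at the preset correlation. The inflammation list was higher (24 of 29 above 0, median 0.06, adjusted p = 0.0446). The endocannabinoid list kept its call with slide as a block (adjusted p = 0.033), and the GABA and inflammation lists lost it (adjusted p = 0.267 and 0.36). Matched by set and arm, the means of the endocannabinoid and GABA lists had that sign on 3 of 4 slides and that of the inflammation list on 2 of 4. Without the set 1 control arms their means were -0.05, -0.02 and 0.01 for the endocannabinoid, GABA and inflammation lists (adjusted p = 0.866, 0.913 and 0.866), against -0.12, -0.14 and 0.07 with all arms. Without the 1 day arms they did not pass either (adjusted p = 0.113, 0.0924 and 0.42). For each of them the adjusted p was 0.809 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone.

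**Figure D2:**
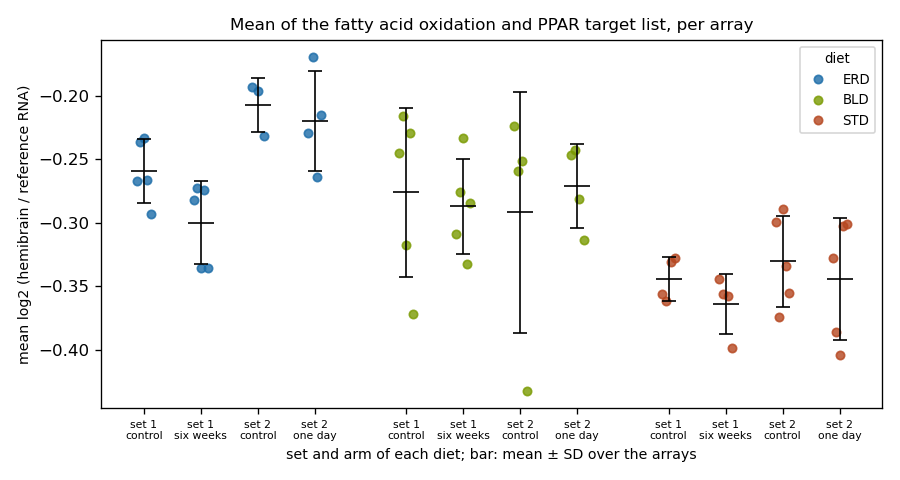
Mean log2 ratio of the 31 measured fatty acid oxidation and PPAR target genes on each array (points), with the mean and SD (bars) of each diet, set and arm. The fitted mean of the list was 0.10 higher in ERD than in STD.

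Genes of fatty acid desaturation, elongation and transport did not pass in ERD against STD. Fads1 and Fads2, the desaturases of polyunsaturated fatty acid synthesis, differed by -0.06 ± 0.10 and -0.01 ± 0.05. The elongases Elovl2 and Elovl5 differed by -0.14 ± 0.19 and -0.04 ± 0.09. Acsl6 (-0.05 ± 0.20), the lipid transporter Mfsd2a (0.09 ± 0.15) and Fabp7 (-0.18 ± 0.18) lay within about their SE. The lipid synthesis genes Srebf1 (-0.08 ± 0.07) and Scd1 (-0.13 ± 0.17) gave adjusted p-values of 0.865 or more. Papola (0.49 ± 0.10), Raly (0.85 ± 0.18) and Cops6 (0.25 ± 0.05) had the next smallest p-values among higher genes, without passing.

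With slide as a block Angptl4 was 0.57 higher (adjusted p = 0.0666), Creg2 was -0.86 (adjusted p = 0.0961), Tatdn2 -0.52 (adjusted p = 0.175), Srp9 -0.37 (adjusted p = 0.3), and Papola alone passed (0.57, adjusted p = 0.0365). On the 4 slides holding both diets of one set and arm the Angptl4 difference ran from 0.47 to 1.14, that of Creg2 from -1.72 to -0.13 and that of Tatdn2 from -1.18 to -0.40, while Srp9 was lower on 2. Without the set 1 control arms 0 genes passed in limma (442 at an unadjusted p below 0.05), and Angptl4 was 0.57 higher (adjusted p = 0.135, where the adjusted p over its alternatives ran from 2.09e-09 to 0.273). The count was 2 without any of the ERD set 1 controls 414 and 416, 6 weeks arrays 418 and 420, set 2 controls 446 and 447, or the STD arrays 434, 435, 441, 442, 469, 470 and 472, while Angptl4 and Creg2 passed in all 35 fits without 1 array. Tatdn2 passed in 12 of the 35 and Srp9 in 17. Srp9 was -0.17 without the set 1 control arms.

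The second comparison set the balanced diet against the standard diet. In BLD, 127 genes were higher and 94 lower. Angptl4 was higher by 0.51 ± 0.09 (adjusted p = 0.00696), in 18 of 18 arrays above the STD median. Slc38a2, an amino acid transporter, was higher by 0.50 ± 0.09 (18 of 18), and Ly6a, a marker of brain endothelium, by 0.54 ± 0.09 (17 of 18; adjusted p = 0.00413). Other large rises were those of Raly (0.72 ± 0.17, and 0.24 with an adjusted p of 0.814 without the set 1 control arms), Nckap1 (0.63 ± 0.16), Dact2 (0.53 ± 0.12), Apobec3 (0.50 ± 0.13) and Pfkl, the liver-type phosphofructokinase (0.49 ± 0.12).

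The largest falls in BLD were those of Dock3 (-0.76 ± 0.20), Creg2 (-0.76 ± 0.15), Oprl1, the nociceptin receptor (-0.65 ± 0.15), Wscd2 (-0.61 ± 0.14), Katnal1 (-0.60 ± 0.14), the metalloproteinase inhibitor Timp2 (-0.54 ± 0.14), the Wnt pathway transcription factor Tcf7l2 (-0.52 ± 0.13) and Chadl (-0.50 ± 0.10). Dock3 divided by scan day in every diet, with log2 ratios of 1.67 to 2.51 on the 16 arrays of day 2 and 3.04 to 4.21 on the 37 of day 1. Day 2 held more BLD than STD arrays, so the fall of Dock3 followed scan day at least in part. Among lipid genes Cpt1a, which admits fatty acids to mitochondrial oxidation, rose by 0.20 ± 0.05 and Hadha, of the same pathway, by 0.23 ± 0.06. The cholesterol synthesis gene Mvd rose by 0.36 ± 0.08, while the sterol carrier Stard4 fell (-0.32 ± 0.07). The ribosomal protein gene Rpl3 rose (0.34 ± 0.07), and Dnm1 (-0.33 ± 0.08) and Prdx6 (-0.34 ± 0.07) fell. The ribosomal list as a whole did not pass (mean 0.01, adjusted p = 0.779). The block for slide put it below 0 in BLD (mean -0.12, adjusted p = 8.51e-09, and adjusted p = 0.76 with an estimated correlation). Fads1 was 0.31 ± 0.10 higher without passing (adjusted p = 0.115), and the adjusted p of Fads2, Elovl2, Elovl5, Acsl6, Mfsd2a, Fabp7, Srebf1 and Scd1 was 0.66 or more.

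The fatty acid oxidation and PPAR target list did not pass in BLD (22 of 31 above 0, median 0.05, adjusted p = 0.142), nor between ERD and BLD (18 of 31 above 0, adjusted p = 0.235). The block for slide gave the ERD and BLD difference an adjusted p of 0.0251 (mean 0.06 against 0.03), and 0.152 with an estimated correlation. Mitochondrial respiratory chain genes were lower in BLD at the preset correlation, with 44 of 62 below 0 and a median of -0.08 (adjusted p = 0.00698, and adjusted p = 0.409 with an estimated correlation). No member passed over all genes; adjusted over the list alone 2 rose and 3 fell. The list had an adjusted p of 0.000348 with slide as a block (0.28 with an estimated correlation), and its mean lay below 0 on 4 of 4 slides, matched by set and arm. It did not pass without the 6 weeks arms (adjusted p = 0.125).

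With slide as a block 0 genes passed in limma (1297 at an unadjusted p below 0.05, smallest adjusted p 0.305). All 221 genes kept their sign. They were called on the same arrays, so kept signs give no independent support, here or in the comparisons below. Several of the genes named above were then much smaller: Dock3 -0.17, Oprl1 -0.17, Wscd2 -0.21, Katnal1 -0.38, Tcf7l2 -0.29, Dnm1 -0.22, Apobec3 0.23, Rpl3 0.19, Hadha 0.11 and Cpt1a 0.06 (0.055). On the 4 slides holding both diets of one set and arm Cpt1a had the sign of the call on 1 (mean -0.04) and Dock3, Oprl1 and Wscd2 on 2. Angptl4 (0.02 to 0.74), Slc38a2, Ly6a, Nckap1, Dact2, Apobec3, Pfkl, Rpl3, Creg2, Timp2 and Prdx6 had it on all 4, and the other named genes past the threshold on 3. Without the set 1 control arms Dact2 was 0.33 and Timp2 -0.35, and without the set 2 controls Katnal1 was -0.28 and Tcf7l2 -0.32. Other passing probes of Timp2 (0.05), Tcf7l2 (0.02 and 0.10) and Prdx6 (3 probes, 0.02 to 0.14) went the other way, and those of Dock3 (-0.02), Dnm1 (-0.01) and Cpt1a (0.04) were near 0. Of the 221 genes 63 had another passing probe, which had the same sign for 41 and a median ratio of 0.193 to the called probe's difference. The split of 127 higher and 94 lower was 191 and 384 with Agilent's processed signals, 348 and 795 with the hemibrain channel alone, 180 and 259 with the series matrix, and 125 and 154 with ratios scaled between arrays. It was 1135 and 422 with array weights and 629 and 338 with the control arms alone. The count was 0 without the set 1 control arms (1697 at an unadjusted p below 0.05) and 0 without the set 2 control arms (2073). It was 491 without BLD set 2 control 458 and 458 without STD 1 day 473. It was 83 and 88 without BLD 1 day 460 and 461, 91 and 84 without STD set 1 controls 433 and 435, 98 and 147 without STD 6 weeks 440 and 441, 79 without STD set 2 control 466, and 134 and 90 without STD 1 day 471 and 472.

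Between ERD and BLD, 10 genes were higher in ERD and 86 lower. Tcf7l2 (0.58 ± 0.13), Ino80b of a chromatin remodelling complex (0.57 ± 0.12), Alkbh7 (0.35 ± 0.08), the peroxisomal gene Pex11a (0.29 ± 0.07), Stard4 (0.29 ± 0.07) and Ppil1 (0.21 ± 0.05) were higher. Htr2c, the serotonin 2C receptor, was lower by the most (-0.95 ± 0.23, 17 of 17 arrays below the BLD median). It was followed by Nckap1 (-0.74 ± 0.17), Tusc3 of the oligosaccharyltransferase (-0.72 ± 0.12), Tmx4 (-0.70 ± 0.15), Cd200 (-0.69 ± 0.17), Cnbp (-0.66 ± 0.13), Atl1 (-0.63 ± 0.13) and the kinase Map2k1 (-0.62 ± 0.12). The chaperone Hsph1 was -0.40 ± 0.09. Fads1 was -0.37 ± 0.10 without passing (adjusted p = 0.0818), and the adjusted p of Fads2, Elovl2, Elovl5, Acsl6, Mfsd2a, Fabp7, Srebf1 and Scd1 was 0.582 or more.

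At the preset correlation the mural cell list (11 of 12 above 0, median 0.10, adjusted p = 0.00758, and adjusted p = 0.25 with an estimated correlation) was higher in ERD than in BLD. The respiratory chain list was higher too (36 of 62 above 0, median 0.03, adjusted p = 0.0317, and adjusted p = 0.579 with an estimated correlation). Both lists lost the call with slide as a block (mural adjusted p = 0.065, respiratory chain adjusted p = 0.0631), and on slides, matched by set and arm, the mural list had its sign on 1 of 3 (-0.07 to 0.04) and the respiratory chain list on 2 of 3. Neither passed without the 1 day arms (adjusted p = 0.058 and 0.0673), nor did the respiratory chain list without the set 1 controls or the 6 weeks arms (adjusted p = 0.08 and 0.165). With slide as a block 51 genes passed, 39 of them shared with the 96, and all 96 kept their sign. Alkbh7, Stard4, Tusc3, Tmx4, Atl1, Map2k1 and Hsph1 passed, and Tcf7l2, Ino80b, Pex11a, Ppil1, Htr2c, Nckap1, Cd200 and Cnbp did not (adjusted p 0.053 to 0.133). Nckap1 and Tmx4 had their sign on 2 of 3 slides, matched likewise. Other passing probes went the other way for Tcf7l2 (-0.14 and -0.01), Alkbh7 (-0.02) and Hsph1 (0.04), and that of Htr2c was -0.05. Tcf7l2 was 0.35 without the set 2 controls. The block for slide gave Tusc3 -0.79 (adjusted p = 0.0121), and on the 3 slides it ran from -1.37 to -0.36. Of the 96 genes 23 had another passing probe, which had the same sign for 12 (median ratio 0.0432). The split of 10 higher and 86 lower was 206 and 311 with processed signals, 375 and 206 with the hemibrain channel alone, 331 and 1268 with array weights, and 77 and 169 with scaled ratios. The count was 0 without the set 1 control arms (1757 at an unadjusted p below 0.05), 190 without the 6 weeks arms, 20 without the set 2 controls and 2 without the 1 day arms. Leaving out single arrays gave 399 (BLD 457), 239 (ERD 451), 159 (ERD 417) and 150 (BLD 425). It gave 29 and 63 (ERD 445 and 447), 60 and 62 (ERD 420 and 422), 55 and 50 (ERD 450 and 453), and 62 and 58 (BLD 461 and 462).

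ERD and BLD were both compared with the same STD arrays. Across genes, which are not independent replicates, the differences from STD correlated with r = 0.485, and 100 simulations without any effect gave a mean r of 0.490 (0.470 to 0.515). The covariance was 0.00888 against 0.00541 in the simulations (0.00505 to 0.00585), and 66.4% of genes had the same sign against 66.2%. The simulated genes were drawn independently of each other, so that range does not allow for correlated genes. Angptl4, Creg2 and Tatdn2 made up the 3 calls shared in direction. The simulations called at most 2 genes in a comparison, so their count of 0 shared calls tests nothing, and independent lists would share 0.00553 higher and 0.0123 lower genes. With the STD arrays divided at random between the comparisons, done a single time, r was 0.404, the covariance 0.00813, and neither comparison had a call. No simulation was run for divided arrays. The simulated r of 0.490 is for shared arrays and is no reference for 0.404.

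The 6 weeks arm was compared with the control arm of set 1 in 14 arrays each. Averaged over the 3 diets, 41 genes were higher and 18 lower. Hmgb1, a chromatin protein, was higher by 1.25 ± 0.25 (adjusted p = 0.00959), in 14 of 14 arrays above the median of all controls. Dgkg (0.87 ± 0.20), the arginine methyltransferase Prmt1 (0.63 ± 0.14) and Garnl3 (0.37 ± 0.08) were higher too. Raly, an RNA-binding protein, was lower by the most (-1.22 ± 0.20, adjusted p = 0.00388), in 14 of 14 arrays below the median of all controls. Both medians pool the diets, and 10 of the 14 controls were ERD or BLD arrays. These counts therefore do not show a difference within STD. Cntfr, the ciliary neurotrophic factor receptor (-1.19 ± 0.26), Ccdc190 (-0.83 ± 0.17), Rab5c (-0.78 ± 0.16), Lsm14b (-0.75 ± 0.14), Erf (-0.46 ± 0.10), Lamtor4 (-0.44 ± 0.10), Zmynd19 (-0.44 ± 0.08), Folr1 (-0.37 ± 0.08) and Hadha (-0.29 ± 0.07) were lower.

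The size of the difference varied by diet. In BLD, Raly had a log2 ratio of 0.76 ± 0.12 in set 1 controls (SD, n = 5) and -1.64 ± 0.26 in 6 weeks arrays (n = 5). In ERD it was 0.55 ± 0.26 and -0.79 ± 0.66, and in STD -1.37 ± 0.62 and -1.30 ± 0.84 (n = 4 each). The set 2 controls, at -1.44 ± 0.31 in ERD (n = 3) and -1.35 ± 0.46 in BLD (n = 4), lay near the 6 weeks arrays. The median difference of the 59 genes, taken in the direction of the call, was 1.38 in ERD and BLD and 0.00 in STD (-0.00263). No gene passed the test of a difference between diets in limma, which gave 0 genes, 1314 at an unadjusted p below 0.05 and a smallest adjusted p of 0.337. That count was 7 without ERD control 415 and 1 without ERD control 417.

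**Figure D3:**
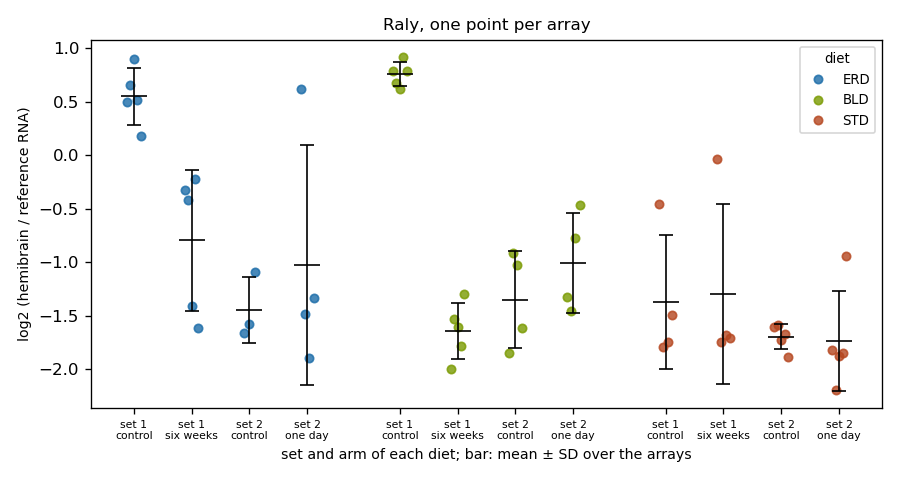
Raly log2 ratio of hemibrain over reference RNA on each array (points), with the mean and SD (bars) of each diet, set and arm. The set 1 controls of ERD and BLD had means of 0.55 and 0.76, and the means of the other 10 groups ran from -1.74 to -0.79.

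Within ERD, 118 genes were higher and 67 lower in the 6 weeks arm. The largest rises were those of Fam205a2 (2.84 ± 0.64), Stk25 (2.16 ± 0.56) and the neuronal microtubule protein Map2 (2.10 ± 0.54), and the largest falls those of Smo (-2.58 ± 0.65), Pdik1l (-2.52 ± 0.61) and Cdc27 (-2.34 ± 0.61). The glutamate transporter Slc1a2 (1.27 ± 0.30), the myelin gene Cldn11 (1.62 ± 0.41), Gabbr1 (1.21 ± 0.27), Txnrd1 (0.83 ± 0.17), Dnmt3a (0.82 ± 0.18) and Abhd4 (0.63 ± 0.15) were higher, and the choroid plexus gene Folr1 (-0.55 ± 0.13) lower. None of these ERD genes passed with slide as a block (smallest adjusted p 0.139), with Smo at -1.48, Pdik1l at -1.22, Cdc27 at -1.05 and Slc1a2 at 0.78. Other passing probes gave -0.25 for Smo, -0.05 for Cdc27, 0.57 for Map2, 0.29 to 2.04 for Fam205a2, and -0.13 and 0.78 for Gabbr1. Without control 413 Map2 was 1.34 (adjusted p = 0.131) and Gabbr1 0.79 (adjusted p = 0.0823). On the 2 slides with both arms Map2 was 0.12 and 5.23 and Stk25 0.77 and 4.50.

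Within BLD, 30 genes were higher and 22 lower. Raly (-2.40 ± 0.33, adjusted p = 8.73e-05), Cntfr (-2.48 ± 0.43), Celf3 (-2.16 ± 0.46) and Zic2 (-0.99 ± 0.23) were lower and Hmgb1 (1.98 ± 0.41) and Pde5a (1.43 ± 0.33) higher. ERD and BLD shared 29 calls in direction, where independent lists would share 0.154 higher and 0.0642 lower genes. That reference ignores correlation between genes and the slides. Slide 8 held ERD set 1 controls 414, 415 and 416 and BLD set 1 controls 424 and 425, but no 6 weeks array. With slide as a block 2 genes passed in ERD and 13 in BLD, so slide is not told apart from the arm in the shared calls. Within STD limma called 0 genes (99 at an unadjusted p below 0.05), with Col27a1 (0.42 ± 0.16), Fam124b (0.65 ± 0.25), Cdc14b (0.37 ± 0.14), Wdr31 (-0.65 ± 0.20) and Slc30a3, a zinc transporter of synaptic vesicles (-0.61 ± 0.20), among the smallest p-values, and Drd2, with a p-value among them too, not well above background on any of the 4 STD 6 weeks arrays. Within ERD, BLD and STD the adjusted p of Fos, Arc, Fkbp5, Sgk1, Crh and Bdnf was 0.296 or more.

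Neuron markers were higher in the 6 weeks arm over the 3 diets, with 13 of 14 above 0 and a median of 0.20 (adjusted p = 0.00777). Astrocyte markers (13 of 16, median 0.15, adjusted p = 0.00822) were higher too, and both adjusted p-values were 0.511 with an estimated correlation. GABA genes (21 of 26, median 0.13, adjusted p = 0.00822), ribosomal protein genes (35 of 51, median 0.05, adjusted p = 0.00844) and presynaptic genes (21 of 26, median 0.09, adjusted p = 0.0264) had adjusted p-values of 0.922 with an estimated correlation. Desaturation and elongation genes (17 of 23, median 0.11, adjusted p = 0.0483) had an adjusted p of 0.511 with it. In ERD, BLD and STD the list means were 0.52, 0.10 and -0.03 for neurons, 0.38, 0.03 and 0.01 for astrocytes, 0.59, -0.06 and -0.09 for GABA, 0.37, -0.03 and -0.08 for presynaptic genes, and 0.25, 0.02 and -0.01 for desaturation. These 5 lists passed in ERD and not in BLD or STD, and all 5 differed between ERD and STD at the preset correlation (adjusted p 1.12e-05 to 0.0163, and 0.247 with an estimated one). That difference held with slide as a block for GABA (adjusted p = 0.000963) and was lost for the other 4 (0.0584 to 0.314). Between ERD and BLD the GABA, presynaptic and astrocyte lists differed (adjusted p = 1.05e-05, 0.00112 and 0.0186, and 0.39 with an estimated correlation), GABA alone with slide as a block (0.00145), while the neuron and desaturation lists did not. Ribosomal genes (0.04, 0.10 and 0.06) passed in BLD at the preset correlation (adjusted p = 0.00672, and 0.949 with an estimated correlation). The neuron (adjusted p = 0.0196), GABA (0.0196) and ribosomal (3.15e-05) lists kept their calls with slide as a block. The desaturation (adjusted p = 0.0795), astrocyte (0.132) and presynaptic (0.622) lists lost theirs, with the presynaptic mean going from 0.088 to 0.00876. With an estimated correlation as well the adjusted p of all 6 was 0.907. Matched by diet, the mean lay above 0 on 4 of 5 slides for the desaturation and ribosomal lists, on 3 for neurons and astrocytes, and on 2 for the GABA and presynaptic lists. Of the activity and glucocorticoid genes, Fos, Arc, Fkbp5, Sgk1, Crh and Bdnf lay between -0.07 and 0.17 with adjusted p-values of 0.77 or more.

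With slide as a block 0 genes passed over the 3 diets (1308 at an unadjusted p below 0.05), 2 in ERD and 13 in BLD, and the 59 genes kept their sign. Raly in BLD was then -2.37 (adjusted p = 0.00443) and ran from -2.78 to -2.09 on 3 of 3 slides. Cntfr (-2.27) and Celf3 (-2.24) passed in BLD too, while Zic2, Hmgb1 and Pde5a did not (adjusted p 0.0972 to 0.118). Matched by diet, Raly was between -2.49 and -1.52 on the 3 slides with ERD or BLD pairs, and 1.76 and 0.00 (-0.0001175) on the 2 with a single STD pair. Hmgb1 and Garnl3 had their sign on 5 of 5 slides, Prmt1 (0.40 with the block) on 3 and the other named genes on 4. Of the other probes of Hmgb1 5 of 6 had its sign (-0.03 to 0.98), and that of Lsm14b was -0.04. Of the 59 genes 11 had another passing probe, all of the same sign with a median ratio of 0.418, and the ratio was 0.273 for 55 genes in ERD and 0.195 for 13 in BLD. The split of 41 higher and 18 lower was 238 and 385 with processed signals and 73 and 177 with scaled ratios. In ERD the split of 118 and 67 was 1069 and 948 with processed signals, 890 and 933 with the hemibrain channel alone, and 219 and 338 with scaled ratios. In BLD the split of 30 and 22 was 80 and 45 with processed signals, 5 and 8 with slide as a block, 2 and 3 with only its groups in the fit, and 1 and 6 with scaled ratios. Array weights gave 280 and 1253 over the 3 diets, 349 and 815 in ERD, and 50 and 276 in BLD. Over the 3 diets the count was 215 without ERD 417, 459 without BLD 423 and 39 without STD 440. In ERD it was 1, 4, 59, 925 and 1011 without the controls 413, 414, 416, 415 and 417, and 11, 10, 5 and 21 without the 6 weeks arrays 419 to 422. In BLD it was 496, 33 and 14 without the controls 423, 425 and 443, and 21, 21, 16 and 11 without the 6 weeks arrays 430, 431, 432 and 444.

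The 1 day arm (13 arrays) was compared with the control arm of set 2 (12 arrays). Erythroid genes were higher as a list: 7 of 7 measured members lay above 0, with a median of 0.30 (adjusted p = 1.45e-10, and adjusted p = 0.00563 with an estimated correlation). Hbb-b1, a beta globin, was 0.89 ± 0.29 higher, Alas2, of haem synthesis in red cells, 0.67 ± 0.23, and Hba-a1, an alpha globin, 0.27 ± 0.15. Immediate early and activity genes were lower as a list, with 24 of 29 below 0 and a median of -0.12 (adjusted p = 3.09e-08, and adjusted p = 0.0124 with an estimated correlation). Egr4 (-0.44 ± 0.21), Dusp6 (-0.32 ± 0.12), Homer1 (-0.30 ± 0.13) and Arc (-0.29 ± 0.14) had the lowest values among its members with Egr2 (-0.30 ± 0.14), and Fos was -0.10 ± 0.13.

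**Figure D4:**
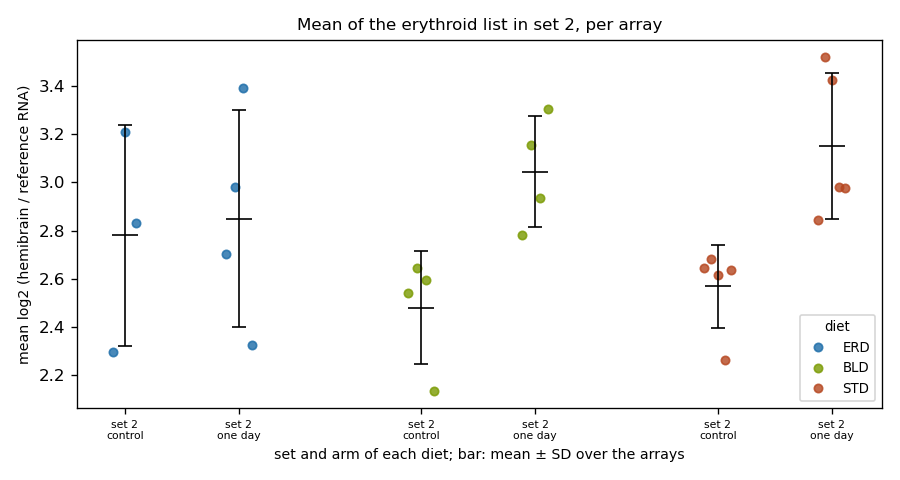
Mean log2 ratio of the 7 measured erythroid genes on each set 2 array (points), with the mean and SD (bars) of each diet and arm. The mean difference of 1 day from control was 0.07 in ERD, 0.56 in BLD and 0.58 in STD.

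**Figure D5:**
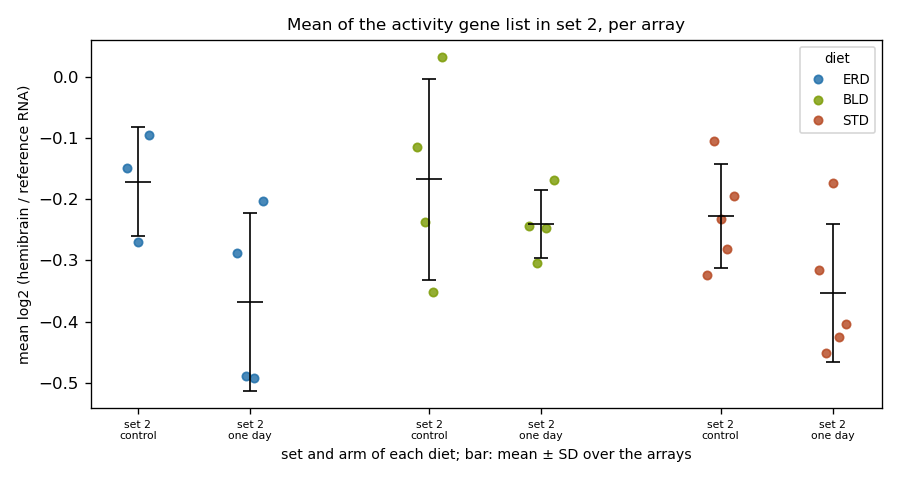
Mean log2 ratio of the 29 measured immediate early and activity genes on each set 2 array (points), with the mean and SD (bars) of each diet and arm. The mean difference of 1 day from control was -0.20 in ERD, -0.07 in BLD and -0.13 in STD.

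No single gene passed in the 1 day arm in the main fit. Over the 3 diets limma called 0 genes (294 at an unadjusted p below 0.05), with Mgp (0.42 ± 0.12), Dancr (0.22 ± 0.07), Dctd (-0.18 ± 0.06) and Cdkn1a (-0.27 ± 0.10) among the smallest p-values, at adjusted p = 1.00. Fkbp5, Sgk1, Crh and Bdnf lay between -0.09 and 0.17. Limma called 0 genes in ERD, BLD and STD too (330, 1037 and 470 at an unadjusted p below 0.05), and 0 in the test between diets (566). Without ERD set 2 control 447 the count in ERD was 1. Array weights, which depend on the order of genes, gave 1502 in ERD (738 higher, 764 lower) and 143 in the test between diets. Among the smallest p-values, none past the threshold, were those of Rtel1 (0.41 ± 0.13), Rnf121 (-0.43 ± 0.14), Vamp1 (-0.81 ± 0.27) and Bfsp2 (-1.05 ± 0.35) in ERD, Limk1 (0.52 ± 0.13), Fbrsl1 (0.91 ± 0.25), Dusp6 (-0.69 ± 0.20) and Plk2 (-0.85 ± 0.27) in BLD, and Alas2 (1.24 ± 0.35), Hbb-b1 (1.51 ± 0.44), Slit3 (-0.35 ± 0.11) and Nupl1 (-0.32 ± 0.10) in STD. Within the 3 diets the adjusted p of Fos, Arc, Fkbp5, Sgk1, Crh and Bdnf was 0.956 or more. Adjusted over the list alone 2 erythroid genes rose and 0 activity genes fell. Heat shock genes (19 of 26 below 0, median -0.05) had an adjusted p of 0.0235, an adjusted p of 0.88 with an estimated correlation, and an adjusted p of 0.0521 with slide as a block. The activity list kept, with slide as a block, an adjusted p of 3.94e-08 (0.0123 with an estimated correlation). The erythroid list had 4.49e-06, and 0.0765 with an estimated correlation. On the 4 slides holding both arms of one diet the erythroid mean was higher on 4 (0.17 to 0.42), the activity mean lower on 3 (-0.23 to 0.02) and the heat shock mean lower on 2. In ERD, BLD and STD the erythroid list had adjusted p-values of 0.365, 0.00203 and 3.14e-06, and of 0.77, 0.646 and 0.117 with an estimated correlation. The test between diets called 15 lists for ERD against BLD, 5 for ERD against STD and 2 for BLD against STD at the preset correlation, 12, 4 and 2 of them with slide as a block too, and 0 with an estimated correlation. With Agilent's processed signals the erythroid list over the 3 diets had an adjusted p of 0.102, where its alternatives ran from 4.13e-24 to that value.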

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

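The tests of the 6 weeks genes below were all chosen after those genes had been seen. The regroupings and the search for arrays far from their group were fixed before.

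Of 143 combinations of 13 measures and 11 groups, 11 held an array far from the others of its group by Dixon's test, where chance gives about 1 in 20. The median net hemibrain signal was 9 on STD set 1 control 434 (others 5.5 to 6), 13 on STD set 2 control 467 (others 5 to 7) and 21 on STD 1 day 473 (others 5 to 9). The mean correlation with other arrays was 0.919 for BLD 6 weeks 432 (others 0.958 to 0.962) and 0.964 for STD set 2 control 469 (others 0.957 to 0.959). Dixon's test looks for 1 array apart from its group and did not flag BLD set 2 controls 457 and 458. Their mean correlations were the lowest of all arrays, at 0.873 and 0.878, against 0.954 and 0.960 for 455 and 456 of that group. On STD 6 weeks 439, 26906 probes were well above background (others 23135 to 23532), and Raly was -0.04 (-0.0368; others -1.75 to -1.68). Creg2 was 3.09 on BLD 6 weeks 431 (others 2.15 to 2.29) and 2.88 on STD 6 weeks 440 (others 2.48 to 2.51). The fatty acid oxidation list mean was -0.43 on BLD set 2 control 458 (others -0.26 to -0.22), and the erythroid list mean was 2.26 on STD set 2 control 468 (others 2.62 to 2.68).

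Other splits of the same arrays were set against each result. For ERD against STD 1 of 100 splits, the real one, gave as many as 4 genes, and the highest other gave 2. That argues against chance but does not exclude it, since 1 of 100 is the smallest share such splits can give. The same holds for BLD against STD (1 of 100, 221 genes, highest other 0), for 6 weeks over the 3 diets (1 of 100, 59 genes, highest other 1) and for 6 weeks in ERD (1 of 100, 185 genes, highest other 72). ERD against BLD (4 of 100, 96 genes) and 6 weeks in BLD (4 of 100, 52 genes) lay under the share of 0.05 set beforehand. Other splits there reached 840 and 229 genes, more than the real ones, which leaves chance open. Any gene passed in 6 and 12 of the other splits, and whether a structure of the samples lies behind them was not tested. Among lists, 1 of 100 splits gave a p as small for the fatty acid oxidation list (real 3.97e-08, lowest other 0.000414), the activity list (1.47e-09 and 1.35e-06) and the erythroid list (3.45e-12 and 3.83e-07). These splits were not drawn within slides and the diets lay unevenly on them, so slide is not excluded by them. With slide as a block the counts were 1 (ERD against STD), 0 (BLD against STD), 51 (ERD against BLD), and 0, 2 and 13 for 6 weeks over the 3 diets, in ERD and in BLD. In limma the counts of 0 had 1297 and 1308 genes at an unadjusted p below 0.05. For the activity list 41 of the other splits had a p below 0.05, for the erythroid list 28 and for the fatty acid oxidation list 13.

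Where the count was 0 every split gives as many by construction, so the splits say nothing about chance there. These were 1 day over the 3 diets (100 of 100, highest other 4478), 6 weeks in STD (35 of 35, highest other 0), and 1 day in ERD (35 of 35, highest other 2251), BLD (35 of 35, highest other 77) and STD (100 of 100, highest other 0). The tests between diets gave 100 of 100 for 6 weeks (highest other 346) and 100 of 100 for 1 day (highest other 3924). Where the highest was 77 or more, few other splits had any gene past the threshold, and their median was 0. Their number was 4 for 1 day over the 3 diets, 2 in ERD and 4 in BLD. It was 2 and 4 for the 6 weeks and 1 day tests between diets. Whether the high counts come from a structure of the samples was not tested.

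The median 6 weeks difference of the 59 genes in STD was -0.00191 of that in ERD and BLD, which argues against an effect of the arm in every diet. In 0.898 of them the set 2 control mean of ERD and BLD lay nearer the 6 weeks mean than the set 1 control mean, against 0.559 of all genes. By diet this held for 58 of the 59 in ERD, 26 in BLD and 23 in STD, so the share for ERD and BLD together rested mainly on ERD. Set 1 controls that stand apart may thus account for them in ERD. In BLD the count, near that of STD, lends this no support, and it stays open there. Of the set 1 controls ERD 414, 415 and 416 and BLD 424 and 425 lay on slide 8, which held no 6 weeks array. ERD 413, 414 and 416 and BLD 424 and 425 had mean correlations with the other arrays of 0.882 to 0.924. Those of the remaining ERD and BLD set 1 controls were 0.941 to 0.954. Other passing probes of the same genes showed a median ratio of 0.418, so signals of single probes could contribute. An effect of the arm within ERD and BLD stays open as well and was not tested apart from these.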

How the results depend on the processing

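The hemibrain channel was dim, and probes too close to background to pass the filter were not tested. Scaling between arrays, brightness as a covariate, the offset of 20, leaving out a set-and-arm group and matching groups within slides were chosen after seeing the data. Except where a value shows it, the cause of a change was not tested. Quantile normalization of average intensity moves no ratio and tests nothing. The REML estimator of array weights stopped before convergence (weights 0.115 to 107) and gives no value.

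Counts that moved by over 1.5 times are given against 4 genes for ERD against STD, 221 for BLD against STD, 96 for ERD against BLD, and 59, 185 and 52 for 6 weeks over the 3 diets, in ERD and in BLD. In that order, Agilent's processed signals gave 9, 575, 517, 623, 2017 and 125, and the hemibrain channel alone gave 7, 1143, 581, 107 and 1823 for the first 5. Without a filter on dim probes ERD against STD had 2 genes, and 6 weeks had 96 in ERD and 31 in BLD. Slide as a fixed block gave 1, 0, 51, 0, 2 and 13. In limma the counts of 0 had 1297 and 1308 genes at an unadjusted p below 0.05. Slide as a random block gave 24 for BLD against STD and 43 for 6 weeks in ERD. Scan day as a block gave 32 for BLD against STD, and 34 and 2 for 6 weeks over the 3 diets and in ERD.

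Array weights (0.166 to 8.35) gave 583, 1557, 1599, 1533, 1164 and 326, and 1502 for 1 day in ERD and 143 for the 1 day test between diets. These weights depend on the order of genes. In a pair of shuffled orders the counts were 592 and 600, 1761 and 2014, 1838 and 2080, 1574 and 1671, 1318 and 1471, and 299 and 343, with 1347 and 1284 for 1 day in ERD and 137 and 133 for the test between diets.

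Only the groups of a contrast in the fit gave 7, 146 and 47 for the diet contrasts and 40 and 5 for 6 weeks in ERD and BLD. The series matrix gave 439 for BLD against STD, 183 for ERD against BLD, and 856 and 1253 for 6 weeks over the 3 diets and in ERD. Control arms alone gave 967 for BLD against STD and 9 for ERD against BLD. Scaling between arrays gave 246 for ERD against BLD, and 250, 557 and 7 for 6 weeks over the 3 diets, in ERD and in BLD. Brightness as a covariate gave 104 over the 3 diets and 2423 in ERD. An offset of 20 gave 7 and 153 for ERD against STD and BLD, and 760 for 6 weeks in ERD.

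Without the set 1 control arms the diet contrasts had 0, 0 and 0 genes in limma (442, 1697 and 1757 at an unadjusted p below 0.05; smallest adjusted p 0.135, 0.116 and 0.170). Angptl4 was then 0.57 and 0.51 above STD in ERD and BLD, against 0.63 and 0.51 with all arms, with fewer arrays. Without the 6 weeks arms ERD against BLD had 190 genes. Without the set 2 controls the diet contrasts had 8, 0 and 20, and without the 1 day arms BLD against STD had 109 and ERD against BLD 2.

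Leaving out 1 array gave 2 to 6 genes for ERD against STD, 79 to 491 for BLD against STD and 29 to 399 for ERD against BLD. For 6 weeks it gave 39 to 459 over the 3 diets, 1 to 1011 in ERD, 11 to 496 in BLD, 0 to 0 in STD and 0 to 7 between diets. For 1 day it gave 0 to 1 in ERD and 0 to 0 over the 3 diets, in BLD, in STD and between diets. Of 4289 named-gene values without 1 array, 3774 kept their side of the threshold, 502 lost the call and 13 gained it. Of 821 list values 649 kept it and 172 lost it.

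The fatty acid oxidation list in ERD against STD (16 of 16 alternatives that gave another test, mean 0.08 to 0.11) and the activity list in 1 day over the 3 diets (12 of 12, mean -0.15 to -0.11) kept their calls. With an estimated correlation 3 of 54 list calls held. The direction of a list in camera is relative to all other genes, so it can turn while the list mean keeps its sign. It turned so with processed signals for striatum in 1 day ERD, with a mean of -0.09 (-0.08597; -0.23 in the main fit), and with the hemibrain channel alone for ribosomal proteins in 1 day ERD, with a mean of 0.02 (0.01771; 0.13 in the main fit). The mean turned sign too for ribosomal proteins in 6 weeks BLD with processed signals, to -0.01 (-0.01284), and for striatum in 6 weeks ERD with the hemibrain channel alone, to -0.04 (-0.0421). The series matrix brings ERD set 2 control 448 and ERD 1 day 454 into 1 day ERD, with mean correlations with the other samples of 0.478 and 0.652. In 1 day ERD it turned the means to inflammation -0.17, glutamate receptors 0.11, presynaptic machinery 0.48, astrocytes 0.31, myelinating oligodendrocytes 0.25, striatum 0.0493 and pyramidal cells 0.14. The presynaptic list then passed in the opposite direction (adjusted p = 0.0293), and the others did not pass (0.214 to 0.696). Scaling between arrays turned them to 0.14 for presynaptic machinery and 0.10 for astrocytes there, neither past the threshold (0.551 and 0.8115). Matched differences within slides turned Cpt1a in BLD against STD to -0.04 (-0.03743) and the mural list in ERD against BLD to 0.00 (-0.002884).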

Other observations

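The tests of slide for both patterns below, and of blood for the 1 day arm, were chosen only after the results had been seen.

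Within ERD 13 lists passed at the preset correlation in the 6 weeks arm, 0 with an estimated correlation and 6 with slide as a block as well. GABA signalling genes lay above 0 for 24 of 26 (median 0.52, adjusted p = 3.18e-06, and adjusted p = 0.286 with an estimated correlation), with Gabbr1 past the threshold over all genes and 4 when adjusted over the list alone. Glutamate receptor and excitatory synapse genes lay above 0 for 30 of 35 (median 0.37, adjusted p = 6.64e-05, and adjusted p = 0.485 with an estimated correlation). Inflammation genes were lower for 24 of 29 (median -0.24, adjusted p = 0.0021, and adjusted p = 0.287 with an estimated correlation). Neuron markers (13 of 14, median 0.41, adjusted p = 0.000566) and astrocyte markers (14 of 16, median 0.35, adjusted p = 0.000566) were higher too, both with an adjusted p of 0.286 with an estimated correlation. So were the striatum (12 of 16, median 0.33, adjusted p = 0.0464) and pyramidal cell (11 of 15, median 0.16, adjusted p = 0.0367) lists, both with 0.62 with an estimated correlation. The astrocyte, striatum and pyramidal lists lost their calls with slide as a block (adjusted p 0.0884, 0.462 and 0.053). All rest on the ERD set 1 controls, which may stand apart: for 58 of the 59 genes of the 6 weeks comparison the ERD set 2 controls lay nearer the 6 weeks mean. Within BLD ependymal and ciliated cell genes were below 0 for 14 of 14 (median -0.23, adjusted p = 0.0397, and adjusted p = 0.949 with an estimated correlation).

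In the 1 day arm ribosomal protein genes went opposite ways in ERD (38 of 51 above 0, median 0.14, adjusted p = 1e-04) and STD (49 of 51 below 0, median -0.16, adjusted p = 4.75e-07), with adjusted p-values of 0.532 and 0.581 with an estimated correlation. The test of that difference gave an adjusted p of 1.08e-09, and 0.634 with an estimated correlation. Ependymal genes in STD were above 0 for 14 of 14 (median 0.22, adjusted p = 9.19e-06, and adjusted p = 0.581 with an estimated correlation), but their mean was -0.17 and 0.40 on the 2 slides with both arms.

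Of the 5 samples with series matrix values alone, 3 stood apart, with a mean correlation with the other samples of 0.478 (ERD set 2 control 448), 0.652 (ERD 1 day 454) and 0.659 (BLD set 2 control 459). The other 2, at 0.818 (STD set 1 control 437) and 0.822 (STD 6 weeks 438), lay within the range of samples with a scanner file (from 0.776, ERD set 1 control 413).

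The fatty acid oxidation and PPAR target list was higher in ERD than in STD by a mean of 0.10. Slide as the whole cause is argued against by its adjusted p of 0.000756 with slide as a block, at a mean of 0.09. Angptl4 alone is argued against by an adjusted p of 6.87e-05 over the other 30 members. Shares of neurons, astrocytes, myelinating oligodendrocytes and endothelium are argued against by an adjusted p of 2.92e-05 with the means of those lists as covariates. Shares of other cell types and of brain regions were not tested. A response of the hemibrain to the diet stays a hypothesis: it was found and tested on the same arrays, and no test here decides it.

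In the 1 day arm erythroid genes were higher and activity genes lower. Slide for the activity list is argued against by adjusted p-values of 3.94e-08 with slide as a block and 0.0123 with an estimated correlation as well. Slide for the erythroid list cannot be told apart from the arm: with the block its adjusted p was 4.49e-06, but 0.0765 with an estimated correlation, and its mean went from 0.405 to 0.346. On slides holding both arms of one diet it was higher on 4 of 4, and the activity mean was lower on 3 of 4. More blood in the 1 day hemibrains may account for the erythroid part: all 7 genes lay above 0, the lowest by 0.109, while the endothelium and mural lists had means of 0.04 and 0.03. The 7 genes, mostly globins, were correlated (estimated correlation 0.315). Their values were known when this test was chosen, so it gives no independent support. Whether both lists share a cause cannot be told apart, since over 25 arrays within groups r was -0.40 (permutation p = 0.102; rho -0.45, p = 0.071; r -0.31 without the 2 arrays farthest from the median). That p had been set beforehand as evidence against a shared cause, which was wrong, as a p that misses a threshold does not show that 2 measures are unrelated.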
